A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

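Transcription was measured by BioGRO-seq, a genomic run-on assay, in the yeast Saccharomyces cerevisiae. Per the labels' protocols, cultures were grown to an OD600 of 0.55, frozen, permeabilised with 0.5% sarkosyl and treated with RNase A, which trims existing RNA. Engaged RNA polymerases were then allowed to extend their transcripts for 5 min at 30 °C with a biotin-labelled UTP. Labelled RNA was purified on streptavidin beads, end-repaired and made into a library with a small RNA kit. There was 1 library from the BY4741 wild type, a haploid laboratory strain of mating type a, and 1 from an XRN1 deletion strain of the Euroscarf collection.

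The authors deposited raw read counts per open reading frame for both libraries in 1 table. The submitters' processing notes name FastQC, Trimmomatic, TopHat2 2.1.1, featureCounts and Subread, and the builds sacCer3 and R64, without their settings. Whether the counting used strand, and how reads with several matches were treated, is not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies, therefore cannot be assigned with certainty. The table held 6448 rows on the 16 nuclear chromosomes, of which 5309 were classed as protein-coding, 566 as putative and 573 as dubious open reading frames. It held 0 rows for rRNA, tRNA, snoRNA, snRNA or mitochondrial genes.

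Gene symbols, positions, lengths, introns, GC content and upstream sequence were taken from the RefSeq R64 annotation. Of the rows, 5831 matched a locus tag there, and the chromosome was the same in all 5831. The rows without a match were 570 dubious, 11 putative and 36 protein-coding ones. The annotated genes hold no UTRs, so gene length is the coding length with introns. Overlaps were sought among the annotated genes, which include few dubious reading frames.

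The libraries held 64934493 counts for the wild type and 46396400 for the deletion strain. Each gene's ratio (deletion strain over wild type) was divided by the raw ratio of the median protein-coding gene with at least 100 counts over both libraries, 0.701. All ratios are therefore relative to the median gene, and a change common to all genes cannot be seen in these counts. Intervals of a ratio are 95% exact conditional (Clopper-Pearson) intervals of 2 counts. They cover counting error only, and the protocols name no molecular identifiers. With 1 library per strain there is no replicate check, and no p-value is given.

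A gene was called higher or lower at a ratio of at least 2 or at most 0.5 with an interval that excluded 1, among genes with at least 100 counts. Gene lists were described by their median log2 ratio over members with at least 20 counts. The 95% interval of a median rests on order statistics over the members. Each median was placed among those of 10000 random lists of the same size, matched in 20 bins of mean log2 scaled count. This mean count was not divided by gene length. A list was called above the 97.5 percentile or below the 2.5 percentile. This describes the 2 libraries and is no test of the strains. Properties of genes were coding length, count per kb, GC content, introns, a TATAWAWR sequence (W is A or T, R is A or G) between 200 and 50 bases upstream of the start codon, and a midpoint within 20 kb of a chromosome end. The numeric properties were cut into 5 groups of equal size, and differences between the outer groups have 95% bootstrap intervals over genes from 2000 draws.

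The named genes are XRN1 and the 4 marker genes of the strain background, the 12 highest and 12 lowest ratios among protein-coding genes with at least 100 counts that overlap no other annotated gene, and members of the lists. From each list these were the 2 with the largest counts and those with the highest and the lowest ratio. These rules, the fixed lists, the comparisons and the main alternatives were set before the data were examined. Some lists and alternatives, and most tests of explanations, were chosen afterwards. Among the fixed lists, 30 had at least 5 measured members and were placed among random lists. The target, the marker genes, the alpha-specific genes and the mitochondrial genome genes were too few. In the cell wall list the symbol MLP1 matched a nuclear pore gene. Of the Gcn4 targets, ARG5,6 was not found. The cell wall and the mitotic and M/G1 lists share 2 genes, and the other fixed lists share none.

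Alternatives were 4 other scalings (total count of all rows, total count of protein-coding genes, edgeR TMM factors and DESeq2 size factors), no count minimum, a minimum of 500 counts, 5 added to each count, overlapping genes left out, random lists matched also on length, and removal of loess trends (span 0.3) on mean count and GC content. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.

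The procedure was tested on simulated data for the comparison of the deletion strain with the wild type, with the means of the 5198 genes and a spread between libraries (SD 0.352 on the log2 scale) set from the observed quartiles. Of 100 genes raised 3-fold, 97% were called higher, and of 100 genes lowered 3-fold, 96% were called lower. Among 4998 unchanged genes, 17 were called higher and 12 lower. The spread was taken from the observed ratios, so it includes any effect of the deletion and is no measure of variation between cultures. Of 200 random lists of 30 unchanged genes, 4.50% fell outside the percentile bounds, and 96% of 100 lists shifted by 0.3 were placed above them. Noise was drawn for each gene independently, so the simulation does not cover lists whose genes vary together between cultures.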

Results

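BioGRO-seq libraries of a wild-type strain and an xrn1 deletion strain of budding yeast were compared, with 1 library per strain. Xrn1 is the cytoplasmic exonuclease that degrades mRNA from its 5′ end, and the series concerns its influence on transcription, both in general on elongating RNA polymerase II and at particular genes. The libraries held 64934493 and 46396400 counts. Protein-coding genes took 96.4% of the counts in the wild type and 96.0% in the deletion strain. The 10 rows with the most counts took 7.95% and 7.36%. The 5198 protein-coding genes with at least 100 counts had a median of 10182 counts over both libraries. Counting error was therefore small for most genes, whereas variation between cultures was not measured.

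The deleted gene matched the labels. XRN1 (YGL173C, chromosome VII, 175527 to 180113) had 41954 counts in the wild type and 53 in the deletion strain, 555-fold lower (95% counting interval 424 to 741). Of the genes that are mutated in the BY4741 background, LEU2 had 1 and 2 counts, URA3 had 4 and 2, and MET17 had 4 and 12. MET17 overlaps YLR302C. HIS3, which is only partly deleted in this background, had 2839 and 2720 counts.

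Most genes kept their place relative to the median gene in the xrn1 deletion strain, while genes induced in the stress response were higher and a-specific mating genes were lower. Of the 5198 genes, 211 were at least 2-fold higher (4.06%) and 79 at least 2-fold lower (1.52%). At 4-fold or more, 49 were higher and 15 lower. The middle part of the genes, between the quartiles, lay between −0.22 and 0.26 on the log2 scale, and 4384 genes (84.3%) were within 1.5-fold of the median gene.

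HSP12 (YFL014W, chromosome VI, 107256 to 107585), a small membrane-protective heat shock protein, had the highest ratio. Its counts were 81 in the wild type and 2166 in the deletion strain, 38.1-fold higher (30.5 to 48.2). BAG7 (YOR134W, chromosome XV, 578564 to 579793) was 26.8-fold higher (23.6 to 30.6). The glucose-repressed hexokinase gene HXK1 (YFR053C, chromosome VI, 253592 to 255049) rested on far more counts, 2862 and 34620, and was 17.2-fold higher (16.6 to 17.9). TMA10 (YLR327C) was 16.8-fold, CPP3 (YDR034W-B) 15.7-fold and USV1 (YPL230W), a zinc finger transcription factor gene, 10.6-fold higher. The other genes of the 12 highest lay between 7.43-fold and 8.95-fold. They were RTA1 (YGR213C), the cardiolipin phospholipase gene CLD1 (YGR110W), the polyamine exporter gene TPO2 (YGR138C), the cell wall mannoprotein gene HPF1 (YOL155C), YNL194C and EGO4 (YNR034W-A). TPO2 was the most transcribed of them, with 16339 and 93398 counts and an 8.15-fold higher ratio (8.02 to 8.29).

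At the low end, PRM6 (YML047C, chromosome XIII, 180017 to 181075), a pheromone-regulated membrane protein gene, had 162 and 10 counts and was 11.4-fold lower (6.02 to 24.1). The cell fusion gene FUS1 (YCL027W, chromosome III, 71803 to 73341) had 3577 and 341 counts and was 7.36-fold lower (6.58 to 8.25). FIG1 (YBR040W) was 5.66-fold lower (3.17 to 10.99), and the pheromone receptor gene STE3 (YKL178C) was 4.65-fold lower (3.25 to 6.84). FRE5 (YOR384W, chromosome XV, 1061564 to 1063648), of the ferric reductase family, was 9.15-fold lower (7.89 to 10.7). The sphingoid base transporter gene RSB1 (YOR049C) was 4.83-fold, CIS1 (YLR346C) 5.07-fold, the oligopeptide transporter gene OPT2 (YPR194C) 5.01-fold and the hypoxic gene ANB1 (YJR047C) 4.42-fold lower. SNZ3 (YFL059W, 6.20-fold lower) and the seripauperin gene PAU3 (YCR104W, 5.61-fold lower) belong to families of near-identical copies, so their counts are uncertain. The same holds for YRF1-7 (YPL283C, chromosome XVI, 280 to 6007), a helicase gene of the repeated chromosome ends. It had 698 counts in the wild type and 0 in the deletion strain, at least 163-fold lower at a floor of 3 counts.

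**Figure D1:**
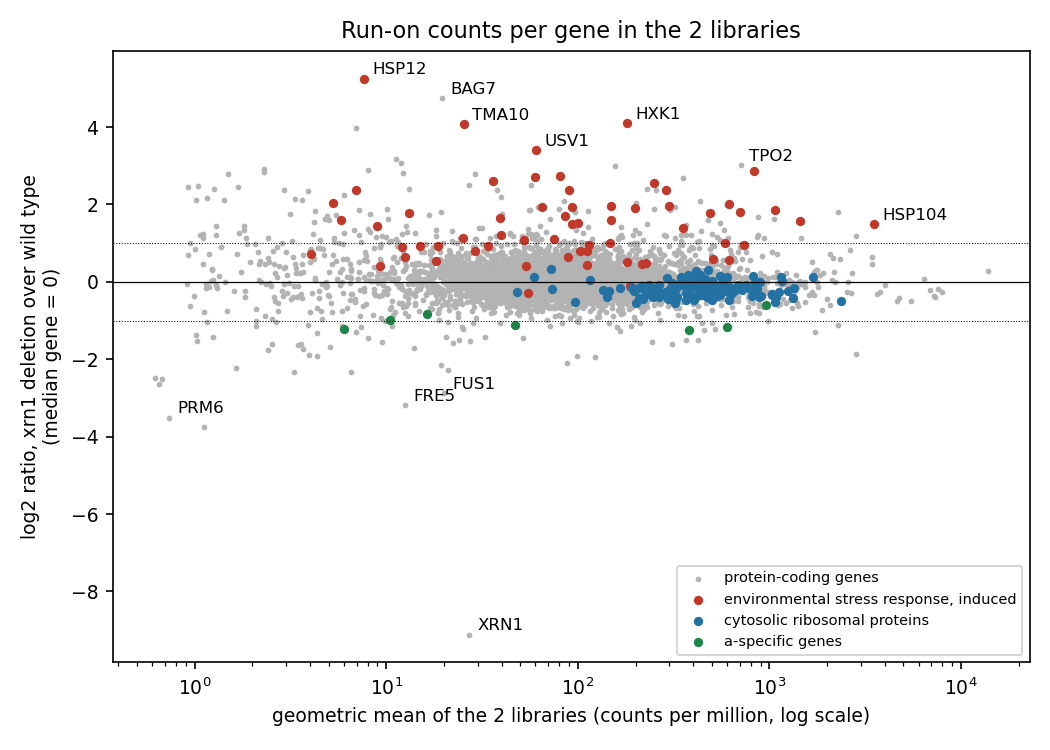
Each point is a protein-coding gene with at least 100 counts over both libraries and at least 1 in the deletion strain. The x axis is the geometric mean of both libraries in CPM on a log scale, the y axis the log2 ratio of the xrn1 deletion strain over the wild type with the median gene at 0, and dotted lines mark 2-fold. Colours mark 3 gene lists: most stress-induced genes lie above 0, most ribosomal protein genes slightly below it, and the a-specific genes below it, while XRN1 lies alone at −9.12.

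Of the 30 lists placed among random lists of matched mean count, 6 had a median above the 97.5 percentile and 7 below the 2.5 percentile. For lists of genes that vary independently, 1.5 would lie outside these bounds. Genes of 1 list may vary together between cultures, which was not measured, so the 1.5 is no error rate for these lists. The genes induced in the environmental stress response stood furthest above. Their median log2 ratio was 1.46 (95% interval 0.95 to 1.78), 60 of the 62 measured members were above the median gene, and 38 were called higher and 0 lower. None of the random lists was as high. The disaggregase gene HSP104 had 136643 and 269910 counts and was 2.82-fold higher (2.80 to 2.83). The glucokinase gene GLK1 was 2.98-fold higher (2.95 to 3.01). PIG2 had the lowest log2 ratio of the list, −0.28. Targets of the heat shock factor and cytosolic chaperones, by contrast, had a median of −0.05 at percentile 52.3. In that list SSE2 was 2.79-fold higher and the only member called. HSP82 was at a log2 ratio of 0.01, SSA2 at −0.27 and HSC82 at −0.53.

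Genes of respiration and of the cell wall were also higher. The nuclear genes of the respiratory chain and ATP synthase had a median of 0.46 (0.28 to 0.63), with 34 of 38 above the median gene and 3 called higher. The cytochrome c isoform gene CYC7 was 4.36-fold higher (3.52 to 5.44), whereas CYC1 was at −0.63. The external NADH dehydrogenase gene NDE1 was at 0.82 and ATP1 at 0.46. Cell wall genes had a median of 0.55 (0.15 to 0.88), with 27 of 34 above the median gene and 9 called higher. The cell wall aspartyl protease gene YPS3 was 3.601-fold higher (3.52 to 3.68). The mannoprotein gene CCW12, which was not called, was at 0.64. The glucan synthase gene FKS1 was at 0.46, and TIR1 was lowest at −0.89. For neither list was any of the random lists as high.

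The other lists above the upper bound were less secure. The mitochondrial ribosomal protein genes had a median of 0.17 (percentile 99.6), and 0 of the 54 members were called. RSM19 was highest at 0.82, RSM7 was at 0.43, MRPL3 at 0.18 and RSM22 lowest at −0.33. Against random lists matched also on length, its percentile was 91.4. The Gcn4 targets of amino acid biosynthesis had a median of 0.11 (percentile 98.4), with 4 members called higher and 2 lower. In it SNO1 was 5.46-fold higher (3.94 to 7.70), SER1 was 2.03-fold lower (1.954 to 2.104), ILV5 was at −0.50 and GCN4 at −0.14. The phosphate regulon had a median of 0.26 (percentile 97.7), with 4 of 17 called higher and 3 lower. The sodium-phosphate cotransporter gene PHO89 was 5.65-fold higher (5.21 to 6.13), the phosphate transporter gene PHO84 2.29-fold higher and PHO8 at 0.72, while PHO12, which has a near-identical copy, was 3.05-fold lower (2.43 to 3.85). Its percentile was 96.0 without genes that overlap another gene, and that of the Gcn4 targets was 79.9 after trends with mean count and GC content were removed, an alternative chosen after seeing the data.

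The a-specific mating genes were lower as a group. All 7 a-specific genes were below the median gene, with a median of −1.12 (−1.24 to −0.59), and 4 were called lower. The alpha-factor receptor gene STE2 was 2.27-fold lower (2.23 to 2.30) and the protease gene BAR1 2.37-fold lower (2.32 to 2.42). The a-factor exporter gene STE6, with the highest ratio of the list, was 1.505-fold lower (1.486 to 1.524). Of the alpha-specific genes, which are too few for a percentile, SAG1 was at −0.43 and STE3 was lower as given above.

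Genes of ribosome production were slightly and broadly lower. Cytosolic ribosomal protein genes had a median of −0.20 (−0.24 to −0.15), with 116 of 137 below the median gene and 0 called. RPL3 was at −0.50, RPS28A lowest at −0.56, RPS22B at 0.11 and RPL15B highest at 0.32. Many of these genes exist as near-identical pairs. Ribosome biogenesis genes had a median of −0.21 (−0.25 to −0.15), with 94 of 118 below the median gene. NSR1 was lowest at −0.79, REA1 was at 0.29, UTP10 at 0.12 and RRP15 highest at 0.47. The subunits of RNA polymerases I and III lay within the bounds (median −0.08, percentile 18.5), with RPA190 at −0.09, RPA135 at −0.17, RPA14 at 0.20 and RPA34 at −0.61.

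Glycolysis, S phase and iron genes were lower too. Glycolysis and fermentation genes had a median of −0.35 (−0.44 to −0.18), with 14 of 16 below the median gene. The glyceraldehyde-3-phosphate dehydrogenase gene TDH2 was 2.16-fold lower (2.15 to 2.18) and its close paralog TDH1 was at 0.31. The treatment of reads with several matches is not known, so the ratios of close paralogs in these lists are uncertain. CDC19, for pyruvate kinase, was at −0.26 and PGK1 at −0.18. Histone genes had a median of −0.39 (−0.55 to −0.09), with 10 of 11 below the median gene. HTA1 was at −0.76, HTB1 at −0.55, HHT2 at −0.40 and the linker histone gene HHO1 at 0.16. Genes of the G1/S transition and DNA replication had a median of −0.38 (−0.51 to −0.16), with 21 of 24 below. The ribonucleotide reductase gene RNR1 was at −0.60, the cohesin gene MCD1 at −0.93 and the cyclin gene PCL1 at 0.74. The iron regulon had a median of −0.25 (−0.57 to 0.05, percentile 0.07), with 17 of 24 below and 2 called lower. Besides FRE5, its scaffold protein gene ISU1 was at −0.60, the siderophore transporter gene ENB1 at 0.43 and the haem oxygenase gene HMX1 at 0.84.

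The mRNA decay and transcription machineries lay within the bounds. Medians were 0.04 for 5′ to 3′ mRNA decay (percentile 66.8), 0.04 for deadenylation (70.5) and −0.10 for the exosome and Ski complex (10.9). Among these lists the scavenger decapping gene DCS1, 2.09-fold higher (2.00 to 2.18), was the only gene called. NAM7 was at 0.04, PAT1 at 0.25, DCP1 at −0.53, CDC39 at −0.25, CCR4 at −0.05, NOT5 at 0.30, CAF130 at −0.43, DIS3 at −0.09, MTR4 at −0.01, LRP1 at 0.36 and RRP6 at −0.34. RNA polymerase II subunits had a median of −0.01 (percentile 48.7), elongation factors and histone chaperones −0.00 (54.8), and SAGA and Mediator −0.04 (26.5), with 0 members called in each. The largest subunit genes RPO21 and RPB2 were at −0.01 and −0.02, RPB4 at 0.58, RPB10 at −0.33, NPL3 at 0.20, SPT6 at 0.10, SPT2 at 0.53, CTK1 at −0.44, TRA1 at −0.01, RGR1 at −0.08, SOH1 at 0.50 and NGG1 at −0.50.

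The remaining lists also lay within the bounds. These were the TCA and glyoxylate cycle (median 0.09, percentile 81.3), the proteasome (0.05, 91.4), the sulfur amino acid pathway (0.07, 73.4), hexose transporters (0.15, 61.5), galactose genes (−0.15, 13.9), seripauperins (0.25, 53.4), ergosterol biosynthesis (0.00, 62.1), mitotic and M/G1 genes (−0.06, 39.5) and meiosis and sporulation genes (0.10, 45.3). Single members stood out in some of them. The hexose transporter gene HXT2 was 6.37-fold higher (6.23 to 6.52), whereas HXT3 was at 0.61 and HXT1 at −0.29. With at least 500 counts the list's median was 1.27, over 6 members, at percentile 99.99. The sulfate transporter gene SUL1 was 5.21-fold higher (4.08 to 6.72), SPO19 was 7.205-fold higher (5.39 to 9.78) and SPS4 was 3.21-fold lower (2.65 to 3.90). PCK1, for phosphoenolpyruvate carboxykinase, was 2.02-fold higher (1.87 to 2.19), and MLS1, for malate synthase, was 2.16-fold lower (1.76 to 2.67).

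**Figure D2:**
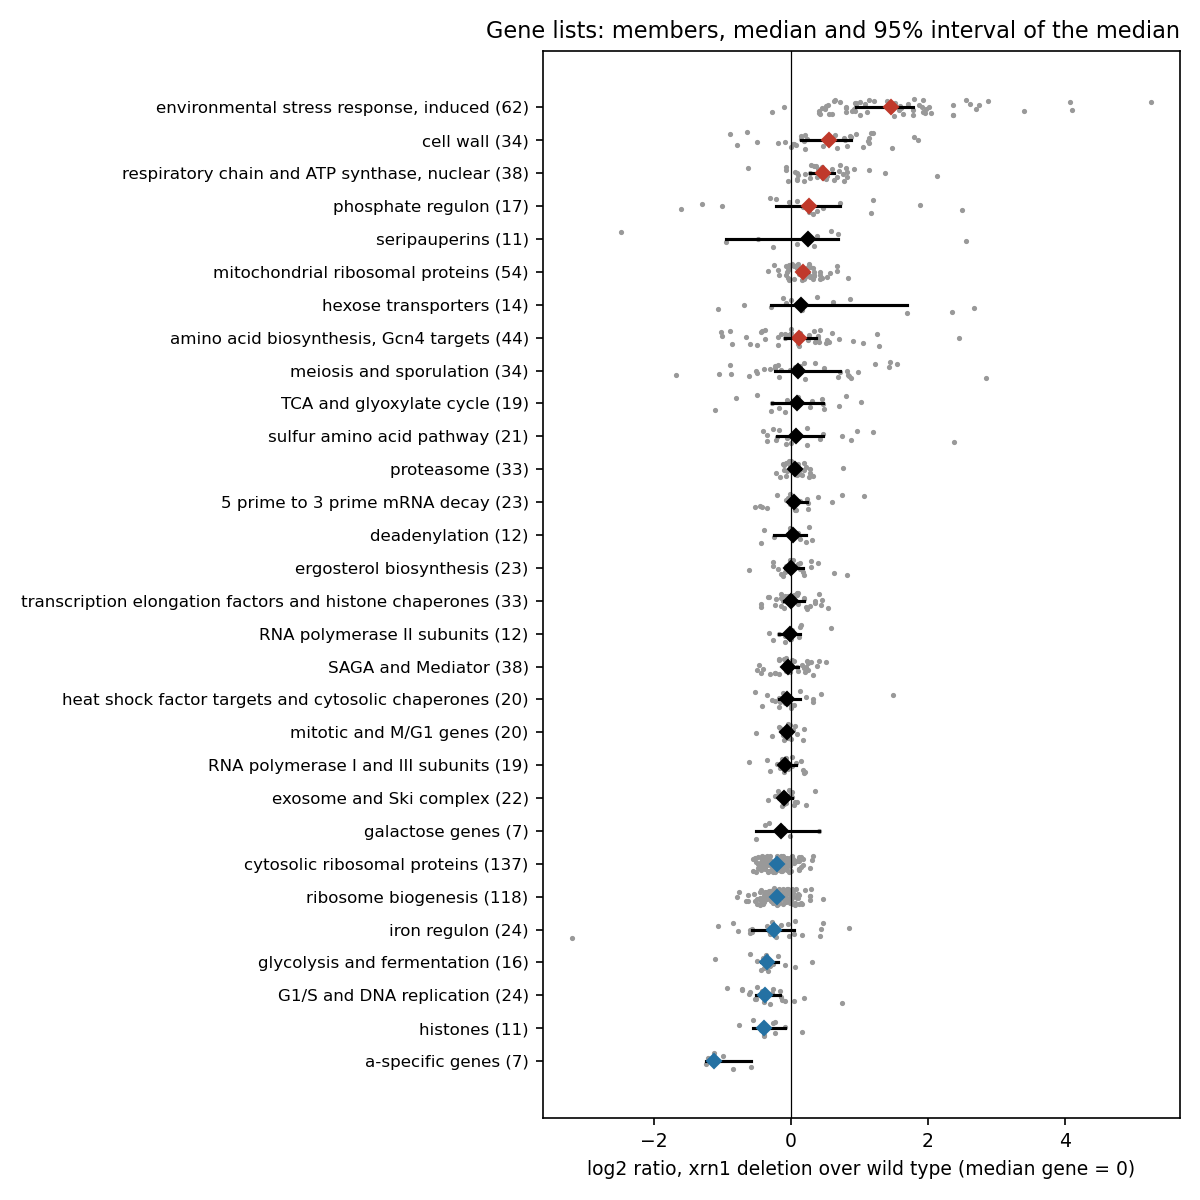
Grey points are the members with at least 20 counts, placed by their log2 ratio of the xrn1 deletion strain over the wild type on the x axis, for each of the 30 lists (number of members in brackets). Diamonds are medians, black bars their 95% intervals over members, with red for lists above the 97.5 percentile of random lists and blue for lists below the 2.5 percentile: the stress-induced genes are highest at 1.46 and the a-specific genes lowest at −1.12.

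Ratios differed little with gene length and structure. In 5 groups of equal size, the 1047 shortest genes (78 to 690 bp of coding length) had a median log2 ratio of 0.12 and the 1047 longest (2144 to 14733 bp) one of −0.06, a difference of 0.18 (0.15 to 0.22). The ratio also rose with GC content, from −0.10 in the group of lowest GC content to 0.16 in that of the highest. After the trends with GC content and mean count were removed, the length difference was 0.050 (0.010 to 0.083). Mean count was not divided by length, so this removal can also take away part of a length difference. Between the groups of lowest and highest count per kb the difference was −0.02 (−0.06 to 0.03). Intron-containing genes had a median of −0.10 (n = 246, percentile 0.010). After removal of the trends the median of all 246 was −0.03 (percentile 8.46). Without ribosomal protein genes, and with the trends kept, it was 0.01 (n = 157, percentile 43.9).

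The median of genes with a TATAWAWR sequence upstream was 0.08 (0.03 to 0.12, n = 1045) against −0.01 for the other 4190 genes, and none of the random lists was as high. After removal of the trends with GC content and mean count the median was 0.025 (−0.013 to 0.080), an interval that includes 0, at percentile 98.96. Of these genes, 107 (10.2%) were called higher and 32 (3.06%) lower. Among the others, 102 (2.43%) were called higher and 45 (1.07%) lower. Without the stress-induced list, 78 of the 107 remained. Subtelomeric genes had a median of 0.05 (n = 122, percentile 48.4), with 8 (6.56%) called higher and 12 (9.84%) lower. Among the other genes, 3.93% were called higher and 1.27% lower. The lower subtelomeric genes include YRF1-7, whose counts are uncertain. The differences between these shares of called genes were not tested.

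**Figure D3:**
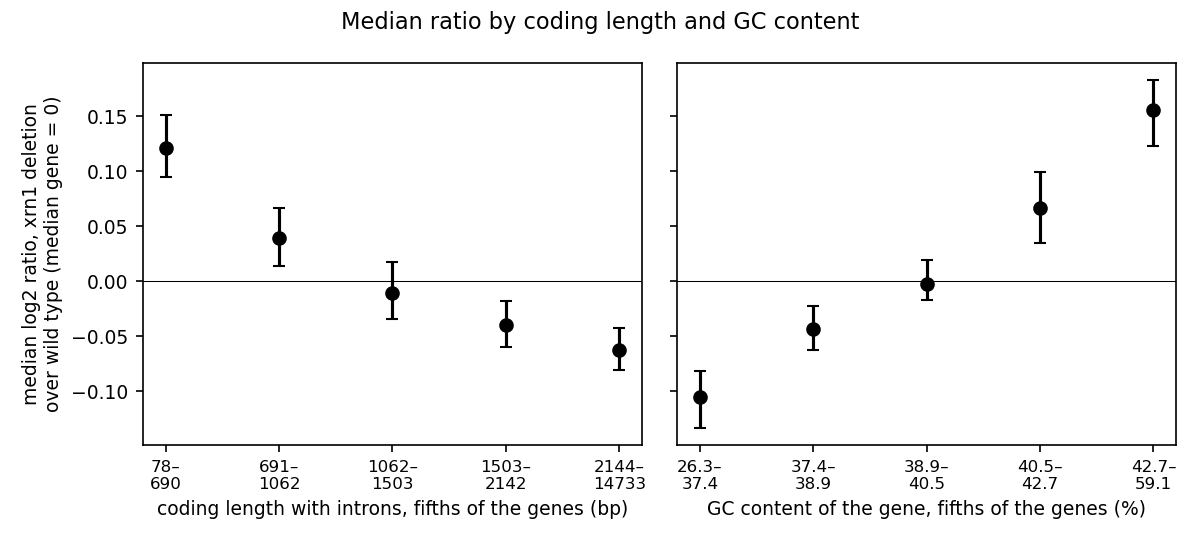
Median log2 ratio of the xrn1 deletion strain over the wild type (y axis) in 5 groups of 1047 genes each, by coding length in bp (left) and GC content in percent (right), with 95% intervals of the median over genes. The medians fall from 0.12 in the shortest to −0.06 in the longest genes and rise from −0.10 to 0.16 with GC content.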

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

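Reading frames outside the protein-coding class, which enter none of the comparisons, took a larger share of the counts in the xrn1 deletion strain than in the wild type. Putative reading frames took 3.36% (95% exact binomial interval 3.36% to 3.37%) against 3.06% in the wild type, and dubious ones took 0.617% (0.615% to 0.619%) against 0.561%. These intervals cover counting error, and the spread between cultures was not measured. Among putative reading frames with at least 100 counts, 31 of 461 were called higher and 21 lower, and among dubious ones 27 of 335 were called higher and 13 lower. The putative frame YGL088W overlaps an annotated snoRNA gene and alone took 477649 counts in the wild type and 388182 in the deletion strain. The dubious frame YFR052C-A was 16.9-fold higher (15.1 to 19.0), close to the 17.2-fold of HXK1, whose systematic name is adjacent. Both were singled out after their values were seen.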

How the results depend on the processing

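No paired analysis was possible because each strain had 1 library, and for the same reason no library could be left out. The share of counts without rRNA was not run, since the table holds no rRNA rows. Over the other scalings, count minimums and added counts, 182 to 229 genes were called higher and 62 to 90 lower. All 211 and 79 genes were called again with no minimum, but they had already passed one, so this could hardly remove them. The scalings shifted the median gene by −0.03 on the log2 scale at most. Trend removal for lists, the lists added later the TATA genes without stress genes and the removal of single trends were chosen after seeing the data.

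Of the list results under the alternatives, those of the lists added later included, 343 kept their side of the percentile bounds, 4 lost their call and 1 gained one. The 4 other scalings shift all genes alike and could not change a percentile, so their results were fixed in advance. With a minimum of 500 counts the hexose transporters came above the upper bound at a median of 1.27, over 6 members instead of 14. Lost calls were the phosphate regulon without overlapping genes (0.26, percentile 96.0), and, against random lists matched also on length, mitochondrial ribosomal proteins (0.17, percentile 91.4) and Gcn4 targets (0.11, percentile 97.5). The Gcn4 targets also lost their call after the trends with mean count and GC content were removed (0.043, percentile 79.9). The same removal ended the call of intron-containing genes (−0.032) and left 0.050 of the length difference, while removal of the GC trend alone left 0.109 and of the mean count trend alone 0.123. The median of the TATA genes moved from 0.079 to 0.025 with both trends removed, to 0.051 with a minimum of 500 counts and to 0.052 under scaling by the total count of all rows, and stayed above the upper bound. The GC difference, lowest minus highest of 5 groups, turned from −0.261 to 0.0048 (interval −0.034 to 0.036), as the correction is built to do. The cause was not tested for the other results. Depth limits the genes of few counts: FIG1, PAU3, SNZ3 and PRM6 had 10 to 13 counts in the deletion strain.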

Other observations

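Further lists were written after a longer listing of genes with high and low ratios had been seen and hold several genes from it, PRM6, FUS1, FIG1, CIS1, RSB1, PDR5, SHM2 and MTD1 included, so their values describe these genes and are no independent evidence of a direction. Of 18 pheromone response genes, 15 were below the median gene and 7 were called lower, with a median of −0.80. The G protein regulator gene SST2 was 2.95-fold lower (2.88 to 3.04), and FAR1 was at −0.995. Of 13 genes of pleiotropic drug resistance, 12 were below the median gene and 7 were called lower (median −1.02). The multidrug transporter gene PDR5 had 351436 and 68047 counts and was 3.62-fold lower (3.59 to 3.65). SNQ2 was 1.59-fold lower, and PDR10 was at 0.30. Of 16 genes of purine and one-carbon metabolism, 14 were below and 5 were called lower (median −0.63). The serine hydroxymethyltransferase gene SHM2 was 2.86-fold lower (2.80 to 2.92), ADE6 was at −0.66, ADE3 at −0.24 and ADE16 at 0.05.

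Of the rows with at least 20 counts in the wild type, 3 had 0 in the deletion strain, among them repeated genes of the chromosome ends. They were YRF1-7 (698 counts), the dubious YHR218W-A (156 counts) and YRF1-5 (60 counts), which would be at least 163-fold, 36.5-fold and 14.0-fold lower at a floor of 3 counts. The putative YHR219W had 186 and 3 counts. Median log2 ratios of whole chromosomes lay between −0.04 (VIII) and 0.09 (IX). Without the stress-induced list, the genes with an upstream TATAWAWR sequence had a median of 0.05 at percentile 99.99, with 78 called higher and 32 lower.

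Of the tests that follow, the predictions for glucose depletion and diploid cells were written before the medians of their lists were seen. Both lists were themselves written after the data had been seen. The predictions of the other tests were written after their values were seen, though the minimum of 500 counts and the scalings had been planned. Low counts do not explain the high stress-induced genes, as 61 of the 62 members had at least 500 counts, with a median of 1.49. With so few members left out, that median could hardly move. Scaling shifts all genes alike, so it cannot make the distance between this list and the median gene. The scalings tried shifted all genes by −0.03 at most on the log2 scale, and the lowest list median under them was 1.44 (0.93 to 1.75). Removal of the trends with GC content and mean count left a median of 1.34, so these trends did not explain the high ratios. Glucose depletion of the xrn1 deletion culture stays open: 13 gluconeogenic and glucose-repressed genes had a median of 0.81 (0.54 to 1.05) and 5 were called higher, among them HXT5 at 1.69. SUC2 was at 0.68, whereas MLS1 was called lower and ICL1 was at −0.49. Of that list, 5 genes also stand in fixed lists, none of them in the stress-induced one. The culture's growth state, which may differ between strains at equal density, and an effect of Xrn1 itself cannot be separated with 1 culture per strain.

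Low mating genes could come from diploid cells in the deletion culture, which repress haploid-specific genes as well. STE4, STE18, STE5, NEJ1 and RME1 had a median log2 ratio of −0.16 and the lowest was at −0.30, which argues against that for these 5 genes. Other mating genes were not part of this prediction. In the pheromone response list GPA1 was at −0.81, FUS3 at −0.53 and STE12 at −0.35, and 15 of 18 genes were below the median gene. Alpha cells would raise alpha-specific genes, whose summed log2 ratio was −0.465 (−0.531 to −0.400). Low counts do not explain the a-specific genes, as all 7 had at least 500 counts, with a median of −1.12 (−1.24 to −0.59). No prediction was set for the pheromone response genes, a list written after the data had been seen. Its median was −0.70 over the 14 members with at least 500 counts, against −0.80 over all 18. That low median therefore does not rest on genes of few counts. Weaker basal signalling of the pheromone pathway in the deletion strain may explain the pattern as a hypothesis and was not tested.

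The difference between short and long genes was 0.17 without strongly changed genes and 0.18 without overlapping genes. Few genes were left out in either case, so the medians could hardly move and these values decide little. Removal of the trends with GC content and mean count left 0.050 (0.010 to 0.083) of the difference. Removal of the GC trend alone left 0.109 (0.073 to 0.148), and of the mean count trend alone 0.123 (0.084 to 0.158), so neither trend by itself took the difference to 0. Mean count was not divided by gene length, so removal of its trend can also take away part of a difference with length. The remainder was above 0 but less than the removed part. Whether length has a part of its own beside both trends therefore cannot be told apart.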
